A study of Mus musculus with 59 samples.

How the data were processed

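The series holds polyA RNA sequencing of the prefrontal cortex of 59 mice, 1 library per mouse, with genotype, line, age and sex given by the labels. The authors aligned reads with STAR to the mm9 genome per the submitters' processing notes, and deposited 1 table of RPKM per gene and library. How reads were counted, which annotation was used and which version of STAR ran are not given in the sources used here. All 59 columns were used and 0 were left out. The table has 18610 rows, of which 15526 were above 0 in every library. Symbols came from the GENCODE vM21 annotation for 17734 identifiers and 874 had none. That annotation is of the GRCm38 build, so it was used for names, neighbours and GC content, and no coordinates are given. No read counts are in the table, but low values rise in steps of 1 read: 1922 of 1923 rows with low values fitted whole reads within 0.05 reads. From these steps a depth of 8.85 to 12.7 M reads per library was estimated. It is an estimate of the reads behind the RPKM scale, and counting error at low values follows from it.

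Values were analysed as log2(RPKM + 0.5), and all log2 differences are on that scale. Genes with at least 0.5 RPKM in at least 10 of the 59 libraries were kept, which left 16403. Linear models were fitted with limma 3.58.1 in R 4.3.3 with a mean-dependent prior of the variance, and p values were adjusted by Benjamini-Hochberg with a threshold of 0.05. All tests were two-sided. The genotype models had a natural cubic spline of log2 age with 3 degrees of freedom, line and sex as covariates. One coefficient of genotype was fitted over all ages, 1 per stage (days 3–12, day 21 and later) and 1 per line, with the differences between stages and between lines as interactions. The change between stages in controls was fitted on the 29 control mice with line and sex, and again on the 30 transgenic mice. Errors of fold changes are standard errors, and errors of RPKM are standard deviations over mice. The 95% confidence limits are from the moderated t distribution.

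The 33 gene lists cover energy and glutamate metabolism, protein synthesis, neuronal function, cell types, neighbouring tissue, activity and stress, and 718 of their 728 members are in the table. They were tested with camera in limma, with the preset correlation of 0.01 and again with a correlation estimated from the data, adjusted over the lists of a comparison. With the estimated correlation 0 lists passed in any comparison, against 46 with the preset. List means per mouse were also permuted within line, and adjusted. Age was predicted by ridge regression on the 1000 genes with the smallest p for age, trained on control mice with each control left out in turn. Single values were compared by permutation of mice within line or stage with 100000 draws, so that the smallest p is 1e-05, and bootstrap intervals used 10000 resamples. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared the tables and figures.

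The fits were tested on simulated data with independent noise per gene, in which 50 genes each were changed 1.2, 1.5, 2 and 3-fold together. At 1.2-fold they recovered 66% over all ages, 50% in days 3–12, 68% from day 21 on, 48% in line a, 50% in line b, 28% in the interaction with stage and 24% in the interaction with line. At 1.5-fold the shares were 94%, 90%, 94%, 82%, 92%, 88% and 82%. With many true changes the adjusted threshold is easier to pass: over all ages 186 genes were called, against 3 in the data. The shares may therefore overstate what the real fits could recover.

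The groups, comparisons, tests, gene lists and most alternatives were fixed before the data were examined. Genes are named by a rule of the same time. For the genotype comparisons these are the genes past the threshold and the next by p up to 10, which are said not to pass. For the stage effect these are the 8 largest rises and falls, for sex the 8 smallest p and for each list up to 4 members with the smallest p, and GLUD2, lincBAC and Glud1 are always named. Some of the genes that this rule names are not reported here. Alternatives varied the pseudocount (0.1 and 1), the filter (none, or a mean of at least 2 RPKM), the scaling (quantile normalization, median ratio), the age curve, array weights, the covariates and the mice included. Chosen after the data were seen were a list of hypothalamic markers and its covariate, the fits without the 10 libraries highest in it, the fits without each of the 59 mice in turn, a covariate for the GC slope of each library, a neuroblast covariate, the agreement of lines without the transgene rows, the age-corrected residual and the change with age from day 55 on. The hypothalamic markers partly overlap genes seen to lead the first component of the residuals. Separate tests of GC content and neuroblasts for H2afx were planned and set aside before they were run, and the same covariates stand among the alternatives. Alternative splicing and alignment to the human BAC were not analysed here, since the table holds 1 value per gene.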

Results

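Gene expression was measured by polyA RNA sequencing in the prefrontal cortex of 59 C57Bl/6 mice, each contributing 1 library. GLUD2 is a human gene for glutamate dehydrogenase that mice lack, and the transgenic mice carried it on a human bacterial artificial chromosome (BAC). The labels named 2 transgenic lines with control mice of their own: 15 control and 15 transgenic mice of line a, and 14 control and 15 transgenic mice of line b. There were 28 females and 31 males. Ages ran from day 3 to day 538, with no mouse between day 12 and day 21, so days 3–12 (12 control and 11 transgenic mice) and day 21 and later (17 control and 19 transgenic mice) were treated as 2 stages. The deposited table held 18610 rows in RPKM (reads scaled to transcript length and sequencing depth), of which 18608 had mouse Ensembl identifiers and 2 were named GLUD2 and lincBAC. RPKM summed to between 232483 and 253607 per library, and the depth estimated from the smallest steps of the values was 8.85 to 12.7 M reads, with a median of 10.2 M. Relative depth was 0.973 ± 0.0653 (SD, n = 30) in transgenic and 1.06 ± 0.0938 (SD, n = 29) in control libraries (two-sided permutation p = 0.00014). The 13 mitochondrial rows made up 7.83 ± 1.28% (SD, n = 12) of the RPKM sum in control mice of days 3–12 and 13.1 ± 1.16% (SD, n = 17) from day 21 on. In transgenic mice the share was 8.54 ± 1.66% (SD, n = 11) and 13.3 ± 0.845% (SD, n = 19).

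Whether the transgene was expressed, and at which ages, was read from its own rows. GLUD2 stood at 6.98 ± 1.78 RPKM (SD, n = 30) in transgenic mice, where the lowest value was 3.33, and at 0.365 ± 0.146 RPKM (SD, n = 29) in controls, where the highest was 0.650. Its level rose with age in transgenic mice, from 5.33 ± 1.57 RPKM (SD, n = 11) in days 3–12 to 7.93 ± 1.06 RPKM (SD, n = 19) from day 21 on (two-sided permutation p = 1e-05, the smallest possible). By age it was 3.52 ± 0.257 RPKM (SD, n = 3) at day 3, 4.69 ± 0.545 (SD, n = 3) at days 6–7, 6.81 ± 0.672 (SD, n = 5) at days 10–12, 8.06 ± 1.16 (SD, n = 5) at days 21–34, 8.38 ± 1.24 (SD, n = 6) at days 55–111, 7.44 ± 0.851 (SD, n = 7) at days 170–319 and 8.09 in the 1 transgenic mouse of day 538. The lincBAC row, whose identity was not given in the sources used here, stood at 9.53 ± 3.46 RPKM (SD, n = 30) in transgenic and 0.0127 ± 0.0337 RPKM (SD, n = 29) in control mice. It rose from 5.85 ± 1.95 RPKM (SD, n = 11) to 11.7 ± 2.002 RPKM (SD, n = 19) between the stages (two-sided permutation p = 1e-05). GLUD2 was higher in line a (7.47 ± 1.95 RPKM, SD, n = 15) than in line b (6.49 ± 1.501 RPKM, SD, n = 15; two-sided permutation p = 0.0455). For lincBAC the order was the reverse, with 8.51 ± 3.48 RPKM (SD, n = 15) in line a and 10.6 ± 3.22 RPKM (SD, n = 15) in line b (two-sided permutation p = 0.0102).

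**Figure D1:**
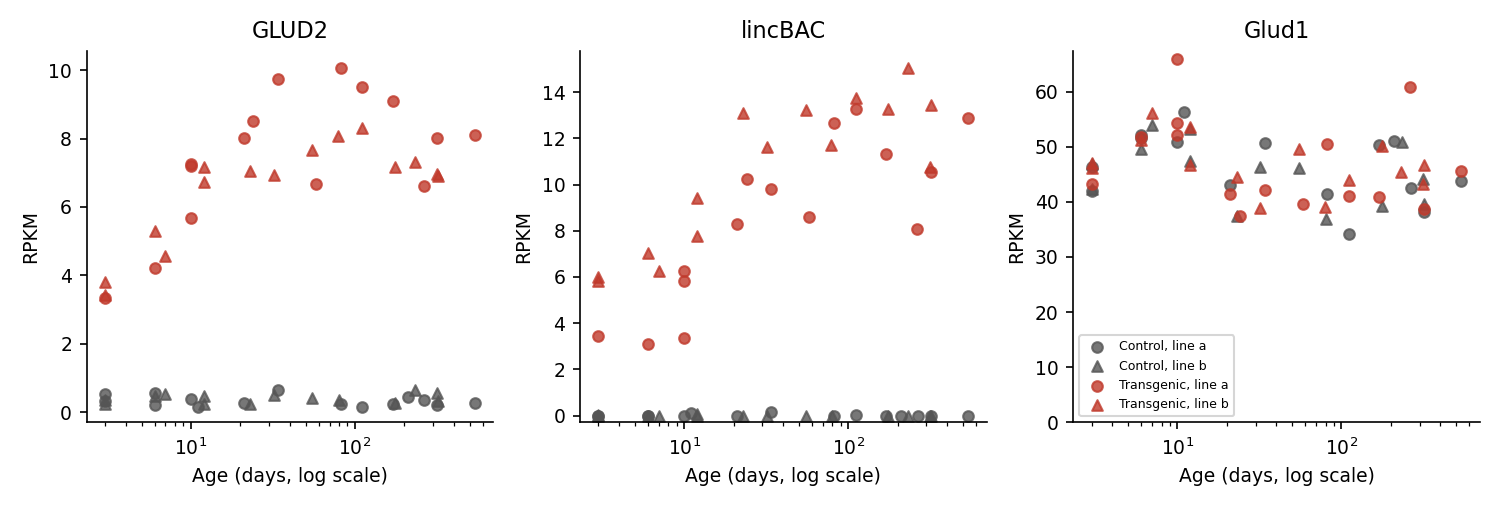
RPKM of GLUD2, lincBAC and mouse Glud1 in each mouse by age. Grey marks control and red transgenic mice; circles mark line a and triangles line b.

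The mouse counterpart Glud1 (ENSMUSG00000021794), the mitochondrial enzyme that converts glutamate to 2-oxoglutarate, was compared because reads of the human gene could align to it. Glud1 stood at 46.9 ± 6.78 RPKM (SD, n = 30) in transgenic and 45.8 ± 5.79 RPKM (SD, n = 29) in control mice, a log2 difference of 0.04 ± 0.05 (SE; adjusted p = 0.9998). In days 3–12 it was 51.6 ± 6.13 RPKM (SD, n = 11) against 49.4 ± 4.49 RPKM (SD, n = 12; two-sided permutation p = 0.327). From day 21 on it was 44.2 ± 5.63 RPKM (SD, n = 19) against 43.3 ± 5.34 RPKM (SD, n = 17; two-sided permutation p = 0.624). Between the stages Glud1 fell in controls by 0.20 ± 0.06 on the log2 scale (SE; adjusted p = 0.0065). By age it was 44.4 ± 2.61 RPKM (SD, n = 4) at day 3, 51.8 ± 1.75 (SD, n = 4) at days 6–7 and 51.9 ± 3.76 (SD, n = 4) at days 10–12. Later it was 44.4 ± 5.54 (SD, n = 4) at days 21–34, 39.6 ± 5.23 (SD, n = 4) at days 55–111 and 44.5 ± 5.5 (SD, n = 8) at days 170–319. The level of day 3 was thus near that of later ages.

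The genotype effect over all ages asked which genes differed between 30 transgenic and 29 control mice once age, line and sex were accounted for. Of 16403 genes tested, 3 were higher in transgenic mice and 0 lower. Besides lincBAC (log2 fold change 4.16 ± 0.09, SE; adjusted p = 4.63e-41) and GLUD2 (3.06 ± 0.07, SE; adjusted p = 5.6e-39), the third was Slc35e2 (ENSMUSG00000042202), a member of a family of solute carriers for nucleotide sugars, at 0.29 ± 0.05 (SE; adjusted p = 0.0105). Controls were near 0 for the transgene rows, so that their fold change was set largely by the pseudocount and ranged from 3.26 to 6.31 for lincBAC and from 2.49 to 3.91 for GLUD2 over the alternatives. Without the 10 libraries highest in hypothalamic markers, Slc35e2 stood at 0.26 with adjusted p = 0.406, against 0.0073 to 0.036 under the other alternatives. The genes next in order did not pass: Pawr, a regulator of apoptosis, stood at -0.25 ± 0.06 (SE; adjusted p = 0.314) and Yrdc, an enzyme of tRNA modification, at -0.11 ± 0.03 (SE; adjusted p = 0.314). Rnaseh2b, a subunit of the nuclease that removes RNA from DNA, stood at -0.15 (adjusted p = 0.860). At unadjusted p under 0.05 there were 454 genes, where 820 would fall by chance. The 95% confidence interval lay within 1.5-fold for 97.8% of genes and within 2-fold for 99.8%. These folds include the pseudocount, which shrinks the fold change of genes with low RPKM. For such genes the interval does not bound the fold change in RPKM. The same holds for the intervals given for each stage. In simulated data the same fit recovered 66% of genes changed 1.2-fold and 94% of genes changed 1.5-fold. That simulation called 186 genes, which eases the adjusted threshold, so these shares may overstate the recovery in the data.

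The effect in days 3–12 asked whether the genotypes differed during early postnatal development. Besides the transgene rows, H2afx (ENSMUSG00000049932), the histone variant H2AX that is phosphorylated at DNA breaks, fell by 0.44 ± 0.09 on the log2 scale (SE; adjusted p = 0.0441). Its level was 12.2 ± 1.93 RPKM (SD, n = 11) in transgenic and 17.3 ± 2.56 RPKM (SD, n = 12) in control mice. From day 21 on H2afx was 12.2 ± 1.98 RPKM (SD, n = 19) and 12.3 ± 2.37 RPKM (SD, n = 17). Several genes fell short of the threshold in days 3–12. The closest, ENSMUSG00000052076, which has no symbol in the annotation used, stood at 0.42 ± 0.09 (SE; adjusted p = 0.0623) and passed in 8 of 16 alternatives (adjusted p = 0.00782 to 0.999 over all 16). Tpt1, a growth-related tumour protein under translational control, stood at -0.40 ± 0.09 (SE; adjusted p = 0.0836). Mrps34, of the small mitochondrial ribosomal subunit, stood at -0.49 ± 0.11 (SE; adjusted p = 0.121), as did the secreted protein gene C1qtnf4 at -0.58 ± 0.13 (SE; adjusted p = 0.121). The immediate early response gene Ier5l stood at -0.50 ± 0.12 (SE; adjusted p = 0.180). Of the 16 alternatives, Tpt1 passed in 4 (adjusted p = 0.00671 to 0.742 over all), and in 2 each Mrps34 (0.0280 to 0.758), C1qtnf4 (0.00108 to 0.742) and Ier5l (0.0186 to 0.501). In this stage 3 genes passed and 988 had an unadjusted p under 0.05, and the interval lay within 1.5-fold for 92.7% of genes. The H2afx call was lost when any 1 of 33 of the 59 mice was left out (adjusted p up to 0.139, log2 fold change -0.48 to -0.41), and the count of genes was 5 without mouse 6, 12 or 34 and 7 without mouse 41. It was also lost without the 10 libraries highest in hypothalamic markers (-0.42, adjusted p = 0.102) and with neuroblast markers as a covariate (-0.36, adjusted p = 0.501), while adjusted p was 0.0072 to 0.0494 under the other settings.

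From day 21 on, the comparison asked whether genotype effects were present in juvenile and adult cortex. Slc35e2 rose by 0.35 ± 0.07 (SE; adjusted p = 0.0223), beside lincBAC (4.53 ± 0.08, SE; 3.604 to 6.703 over the alternatives) and GLUD2 (3.26 ± 0.08, SE; 2.67 to 4.135). The Slc35e2 call from day 21 on was lost in 5 settings (adjusted p = 0.0762 to 0.606), among them the fit without the 2 mice of day 538 (adjusted p = 0.0871), while its log2 fold change stayed at 0.33 to 0.39 in them. It was lost as well when any 1 of 9 mice was left out (adjusted p up to 0.0787, log2 fold change 0.32 to 0.37). The small nucleolar RNA gene Snora78 (0.93 ± 0.24, SE; adjusted p = 0.925) and Mrps27, another mitochondrial ribosomal gene (-0.13; adjusted p = 0.9998), did not pass, though Mrps27 did in 1 of 17 alternatives (adjusted p = 0.0380, against at least 0.9976 in the others). Cdh11, a cadherin of cell adhesion, did not pass (-0.21; adjusted p = 0.9998). At unadjusted p under 0.05 there were 378 genes, and the interval lay within 1.5-fold for 96.2% of genes. With days 21–34 as a stage of their own, 73 genes passed in those 5 transgenic and 4 control mice. That count was 2 without transgenic mouse 43 and 360 without control mouse 13.

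The genotype by stage interaction tested whether the effect differed between days 3–12 and day 21 and later. The lincBAC row differed, with a log2 effect 0.95 ± 0.12 smaller in days 3–12 (SE; adjusted p = 1.41e-06). GLUD2 (-0.52 ± 0.12, SE; adjusted p = 0.804) and H2afx (-0.40 ± 0.11, SE; adjusted p = 0.804) did not pass. Ccl12, a chemokine gene, stood at 0.78 (adjusted p = 0.804), and Epb41l2, a gene of the membrane skeleton, at 0.28 (adjusted p = 0.804). In all, 1 gene passed and 999 had an unadjusted p under 0.05. Without the 10 libraries highest in hypothalamic markers, 2 genes passed, GLUD2 being the second at -0.64, and 3 genes passed without mouse 41.

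The 2 lines were compared to ask which effects were present in both. In line a, Slc35e2 rose from 6.86 ± 0.470 RPKM (SD, n = 15) in controls to 10.7 ± 1.76 RPKM (SD, n = 15) in transgenic mice, a log2 fold change of 0.57 ± 0.06 (SE; adjusted p = 8.07e-11). All 15 transgenic mice of line a exceeded the highest line a control, which stood at 7.81 RPKM. In line b, Slc35e2 was 6.82 ± 0.555 RPKM (SD, n = 14) in control and 6.82 ± 0.584 RPKM (SD, n = 15) in transgenic mice (two-sided permutation p = 0.989). Slc35e2 was also the 1 gene whose effect differed between the lines (0.57 ± 0.08, SE; adjusted p = 2.1e-05). The uncharacterized gene 1110038F14Rik (0.31 ± 0.07, SE; adjusted p = 0.327) did not pass in the interaction. With array weights 2 genes passed there, 1110038F14Rik being the second at 0.35. GLUD2 rose by 3.20 ± 0.10 (SE) in line a and 2.91 ± 0.10 (SE) in line b, with 2.60 to 4.13 and 2.37 to 3.69 over the alternatives. The lincBAC row rose by 3.96 ± 0.12 (SE) in line a and 4.36 ± 0.13 (SE) in line b, with 3.08 to 6.05 and 3.44 to 6.57 over the alternatives. In line b no mouse gene passed, and Rrm2, a subunit of ribonucleotide reductase, stood at -0.33 ± 0.09 (SE; adjusted p = 0.9999). In line a 3 genes passed of 350 at unadjusted p under 0.05, in line b 2 of 498, and in the interaction 1 of 334. Across genes the log2 effects of line a and line b had a Pearson r of 0.124 and a Spearman rho of 0.022. Without the 2 transgene rows r was -0.0097. In days 3–12 r was 0.245, and it was 0.211 without the transgene rows.

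**Figure D2:**
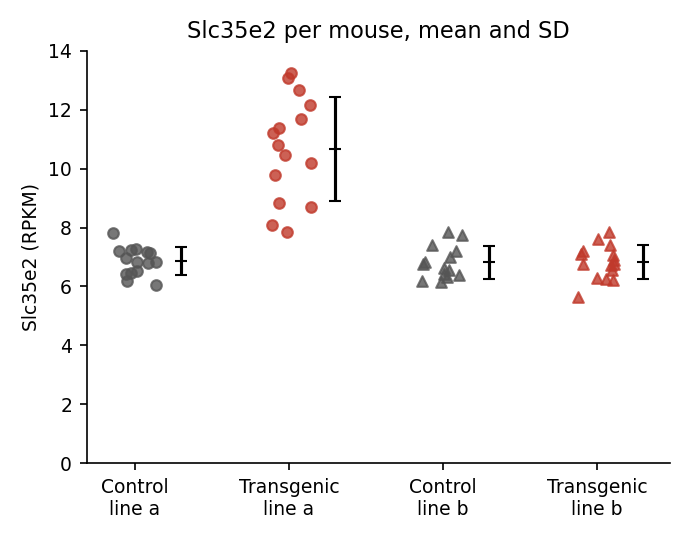
Slc35e2 (RPKM) in each mouse by genotype and line, with the mean and SD of each group.

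Gene lists were used to ask whether genes of energy metabolism, glutamate handling or single cell types moved together between the genotypes. In days 3–12 markers of olfactory bulb and neuroblasts, which label tissue next to the frontal cortex and migrating young neurons, were lower in transgenic mice, with 6 of 10 members past the threshold adjusted over the list alone (FDR = 9.81e-07; adjusted p = 0.366 with an estimated correlation). Among them the transcription factor genes Sp8 (-0.94 ± 0.24, SE; list-alone adjusted p = 0.00285), Eomes (-0.92 ± 0.29, SE; 0.011) and Tbx21 (-0.70 ± 0.25, SE; 0.0249) fell, and these 3 passed whichever mouse was left out. Sp8 was 0.835 ± 0.794 RPKM (SD, n = 11) in transgenic and 2.08 ± 1.44 RPKM (SD, n = 12) in control mice. In the interneuron list, which was not called, Dlx2 (-0.81 ± 0.21, SE; list-alone adjusted p = 0.00468) and Dlx1 (-0.65 ± 0.20, SE; 0.0151), which specify inhibitory neurons, fell in days 3–12, though Dlx1 did not pass without mouse 35 (0.0701). Striatal markers were also called lower (median -0.33; FDR = 0.0136; adjusted p = 0.828 with an estimated correlation), where Ppp1r1b, the dopamine-regulated phosphatase inhibitor of striatal neurons, stood at -1.08 ± 0.48 (SE). The striatal call was lost without control mouse 10 (FDR = 0.0816) and without transgenic mouse 34 (0.0734), 35 (0.102) or 40 (0.0673).

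Interferon response genes were called lower in days 3–12, with 1 of 15 positive (FDR = 3.06e-06; adjusted p = 0.445 with an estimated correlation), and the interferon-induced Ifi27 stood at -0.31 ± 0.10 (SE) and Ifit1 at -0.38 ± 0.15 (SE). Control mouse 10 had the highest mean level of this list, and without it the median effect went from -0.20 to -0.10 (FDR = 0.00256). Genes of the tricarboxylic acid cycle, which glutamate dehydrogenase supplies with 2-oxoglutarate, were called higher with a median of 0.06 and 16 of 18 positive (FDR = 4.89e-05; adjusted p = 0.445 with an estimated correlation). Of these, Sdhd stood at 0.13 ± 0.05 (SE), Ogdh, which uses 2-oxoglutarate, at 0.10 ± 0.04 (SE) and Idh2 at -0.16 ± 0.08 (SE). Oxidative phosphorylation was called higher with a median of 0.04 and 54 of 71 positive (FDR = 4.01e-05; adjusted p = 0.719 with an estimated correlation), the complex I gene Ndufs5 standing at 0.18 ± 0.06 (SE), a call lost without transgenic mouse 38 (FDR = 0.0628, median 0.02). Ketone body use and monocarboxylate transport was called higher with 8 of 10 positive (FDR = 0.0147; adjusted p = 0.445 with an estimated correlation), Oxct1 standing at 0.13 ± 0.06 (SE), and without mouse 38 the median went from 0.09 to 0.06 (FDR = 0.0469). Among glial lists, astrocyte markers were called higher (FDR = 0.00203; adjusted p = 0.445 with an estimated correlation), and the water channel gene Aqp4 stood at 0.47 ± 0.15 (SE; list-alone adjusted p = 0.0483, above the threshold when any 1 of 41 of the 59 mice was left out). Oligodendrocyte precursor markers were called higher (FDR = 0.00887; adjusted p = 0.445 with an estimated correlation), and Gpr17, a receptor of differentiating precursors, stood at 0.35 ± 0.12 (SE; list-alone adjusted p = 0.0319). Both calls were lost without transgenic mouse 38, which left the list at FDR = 0.226 (median 0.08 instead of 0.13) and Gpr17 at 0.204, and Gpr17 was also above the threshold without mouse 4, 5, 7, 33, 36 or 37 (0.0512 to 0.0966). Synaptic vesicle release was called higher with 18 of 26 positive (FDR = 0.025; adjusted p = 0.719 with an estimated correlation), Rab3a standing at 0.08 ± 0.04 (SE), a call lost when any 1 of 10 mice was left out (FDR up to 0.194). Glutamate and GABA metabolism was not called, and its transaminase gene Got2 stood at 0.06 ± 0.03 (SE) and the glutamine synthetase gene Glul at -0.15 ± 0.09 (SE). In all, 12 members of the 33 lists passed in days 3–12 when adjusted over the list alone. When list means per mouse were permuted within line, the smallest p was 0.0578 (adjusted p = 0.805), for olfactory bulb and neuroblasts in days 3–12.

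From day 21 on, striatal markers were called higher with 15 of 15 positive (median 0.25; FDR = 0.000682), the neuropeptide genes Tac1 and Penk standing at 0.27 ± 0.24 (SE) and 0.37 ± 0.35 (SE). The median was 0.12 without control mouse 20, where the call was lost (FDR = 0.0600), and 0.40 without transgenic mouse 56. Cell cycle genes were called lower with 5 of 30 positive (FDR = 0.000294), Rrm2 standing at -0.21 ± 0.08 (SE), and without transgenic mouse 41 the median went from -0.06 to -0.04. Cytosolic ribosomal protein genes (median -0.04; FDR = 0.00206) and ketone body use (median -0.08; FDR = 0.00464) were called lower, with Rplp0 at -0.11 ± 0.06 (SE) and Oxct1 at -0.09 ± 0.05 (SE). The ribosomal call was lost without transgenic mouse 41 (FDR = 0.507, median -0.0166) or 43 (0.360, median -0.0190). Oxidative phosphorylation was called lower with a median of -0.03 (FDR = 0.00206), a call that quantile normalization ended. Each of these 5 lists had adjusted p = 0.987 with an estimated correlation. Over all ages, cell cycle (FDR = 0.000233), olfactory bulb and neuroblasts (FDR = 0.00106) and cytosolic ribosomal proteins (FDR = 0.0331) were called lower and astrocytes higher (FDR = 0.0331), each with adjusted p = 0.949 with an estimated correlation. The ribosomal call over all ages was lost when any 1 of 26 mice was left out (FDR up to 0.321) and the astrocyte call when any 1 of 16 was (up to 0.130). Among their members Sp8 stood at -0.46 ± 0.17 (SE) and Aqp4 at 0.18 ± 0.10 (SE).

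In line a, myelin genes were called higher with 13 of 15 positive (median 0.26; FDR = 0.00498), Mag standing at 0.33 ± 0.26 (SE), and circadian clock genes higher with 13 of 16 positive (FDR = 0.00839), Nr1d1 standing at 0.19 ± 0.09 (SE). In line b neither list was called, and 0 of 15 myelin genes (median -0.10; FDR = 0.410) and 3 of 16 clock genes (FDR = 0.179) were positive. The myelin call in line a was lost without control mouse 7 (FDR = 0.0666), 9 (0.194) or 10 (0.139) or transgenic mouse 38 (0.131), where the median was 0.156 to 0.162, and the median was 0.41 without control mouse 13. The clock call was lost without mouse 6, 7, 41 or 43 (FDR = 0.0639 to 0.0838). Interferon response (FDR = 0.00115), olfactory bulb and neuroblasts (FDR = 0.0224) and heat shock genes (FDR = 0.0224) were called lower there, each of the 5 with adjusted p = 0.948 with an estimated correlation. The interferon call in line a was lost without control mouse 10 (FDR = 0.618, median -0.02 instead of -0.14), and in line b 9 of 15 genes were positive (FDR = 0.91). The other 2 calls were lost when any 1 of 7 and any 1 of 10 mice was left out (FDR up to 0.125 and 0.201). In line b, cell cycle genes were called lower with 4 of 30 positive, and Rrm2 had a list-alone adjusted p of 0.0269, above the threshold when any 1 of 8 mice was left out (up to 0.0794). Astrocytes (FDR = 0.0342) and microglia (FDR = 0.0342) were called higher and olfactory bulb and neuroblasts lower (FDR = 0.038) in line b, each of the 4 with adjusted p = 0.986 with an estimated correlation. These 3 calls were lost when any 1 of 9, 11 and 15 mice was left out (FDR up to 0.138, 0.118 and 0.240).

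Development in the control mice was described as the background of these comparisons, by day 21 and later (n = 17) minus days 3–12 (n = 12). Of 16403 genes, 4905 rose and 6055 fell, 804 and 775 of them by over 2-fold. Genes of the myelin sheath led the rises, with Mobp at 5.51 ± 0.57 (SE), Mal at 5.01 ± 0.36 (SE) and Ermn at 3.87 ± 0.20 (SE). Mobp went from 0.0793 ± 0.0690 RPKM (SD, n = 4) at day 3 to 186 ± 69.5 RPKM (SD, n = 4) at days 21–34 and 115 ± 32.96 RPKM (SD, n = 8) at days 170–319. Among the other large rises were the calcium buffer Pvalb (4.04 ± 0.37, SE), the sodium channel subunit Scn4b (4.37 ± 0.47, SE) and the perineuronal net gene Hapln4 (3.82 ± 0.26, SE). Among the largest falls, the neurite growth gene Dpysl3 fell by 4.69 ± 0.34 (SE), Cd24a by 4.19 ± 0.38 (SE), Dpysl5 by 3.94 ± 0.25 (SE) and the tubulin gene Tubb2b by 3.89 ± 0.32 (SE). The radial glia gene Fabp7 fell by 3.82 ± 0.34 (SE), the imprinted RNA gene H19 by 3.73 ± 0.30 (SE) and the matrix gene Tnc by 3.51 ± 0.29 (SE). Dpysl3 went from 479 ± 21.2 RPKM (SD, n = 4) at day 3 to 7.48 ± 2.11 RPKM (SD, n = 8) at days 170–319. In transgenic mice, tested on their own, 4583 genes rose and 5837 fell. Of these, 4152 rose and 5335 fell in both genotypes, where 1370 and 2155 would be shared by chance, and 0 went opposite ways. The log2 changes of the genotypes had a Pearson r of 0.962 (Spearman rho = 0.949).

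By list, 15 of 15 oligodendrocyte and myelin genes rose (median 3.16; adjusted p = 0.344 with an estimated correlation), and 25 of 27 genes of neurite growth and migration fell (median -1.44; adjusted p = 0.344 with an estimated correlation), among them Stmn2 (-2.11 ± 0.12, SE). Cell cycle genes fell in 29 of 30 cases (adjusted p = 0.583 with an estimated correlation), with the proliferation marker Mki67 at -2.04 ± 0.20 (SE) and Cdk1 at -1.79 ± 0.17 (SE). Of 22 cholesterol biosynthesis genes 18 fell and 1 rose (adjusted p = 0.583 with an estimated correlation), with the squalene epoxidase gene Sqle at -1.34 ± 0.11 (SE). Ketone body use fell in 7 of 10 genes (adjusted p = 0.344 with an estimated correlation), with Bdh1 at -1.81 ± 0.11 (SE), Slc16a1, the transporter of lactate and ketone bodies, at -1.31 ± 0.14 (SE) and Oxct1 at -0.83 ± 0.10 (SE). Of 17 genes of glutamate and GABA metabolism 14 rose and 1, Glud1, fell (adjusted p = 0.583 with an estimated correlation). The glutaminase Gls2 rose by 1.65 ± 0.20 (SE), Glul by 1.61 ± 0.16 (SE), Got1 by 1.26 ± 0.17 (SE) and the GABA-making Gad1 by 0.91 ± 0.11 (SE). In oxidative phosphorylation 38 of 71 genes rose and 5 fell (adjusted p = 0.649 with an estimated correlation), Ndufa12 by 0.55 ± 0.05 (SE). In glycolysis 14 of 21 rose and 3 fell (adjusted p = 0.583 with an estimated correlation), Aldoa by 1.65 ± 0.16 (SE) and Pkm by 0.98 ± 0.07 (SE). In synaptic vesicle release 20 of 26 rose and 3 fell (adjusted p = 0.602 with an estimated correlation), Snap25 by 1.94 ± 0.19 (SE).

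Of 74 cytosolic ribosomal protein genes 61 fell and 2 rose (adjusted p = 0.602 with an estimated correlation), with Rplp0 at -1.41 ± 0.12 (SE). Circadian clock genes rose in 15 of 16 cases (adjusted p = 0.344 with an estimated correlation), with Ciart, a repressor of the clock, at 1.44 ± 0.11 (SE) and Dbp at 1.80 ± 0.16 (SE). All 15 microglia markers rose (adjusted p = 0.583 with an estimated correlation), the complement gene C1qa by 1.21 ± 0.16 (SE) and the protease Ctss by 1.76 ± 0.24 (SE). Astrocyte markers rose in 10 of 15 cases and fell in 1 (adjusted p = 0.602 with an estimated correlation), S100b by 2.81 ± 0.32 (SE). Immediate early genes rose in 13 of 20 cases (adjusted p = 0.602 with an estimated correlation), Fosb by 1.67 ± 0.19 (SE). Interferon response genes rose in 8 of 15 cases (adjusted p = 0.602 with an estimated correlation), Ifit3 by 1.40 ± 0.20 (SE). Heat shock genes rose in 13 of 20 cases and fell in 2 (adjusted p = 0.602 with an estimated correlation), Ddit3 by 1.02 ± 0.07 (SE). Hypoxia genes rose in 9 of 13 cases and fell in 2 (adjusted p = 0.344 with an estimated correlation), the glucose transporter Slc2a1 by 1.17 ± 0.12 (SE). Striatal markers rose in 11 of 15 cases (adjusted p = 0.679 with an estimated correlation), Penk by 2.25 ± 0.40 (SE). Markers of pericytes and meninges fell in 11 of 15 cases and rose in 1 (adjusted p = 0.602 with an estimated correlation), Col3a1 by 2.73 ± 0.24 (SE). Of glutamate transporters and receptors, a list not called, 12 of 30 rose and 8 fell. The NMDA receptor subunit genes Grin2c (2.18 ± 0.23, SE) and Grin2d (-1.43 ± 0.14, SE) went opposite ways. Among genes of the tricarboxylic acid cycle, also not called, 10 of 18 rose and 4 fell, with Sdha at 0.82 ± 0.08 (SE) and Cs at -0.37 ± 0.04 (SE).

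**Figure D3:**
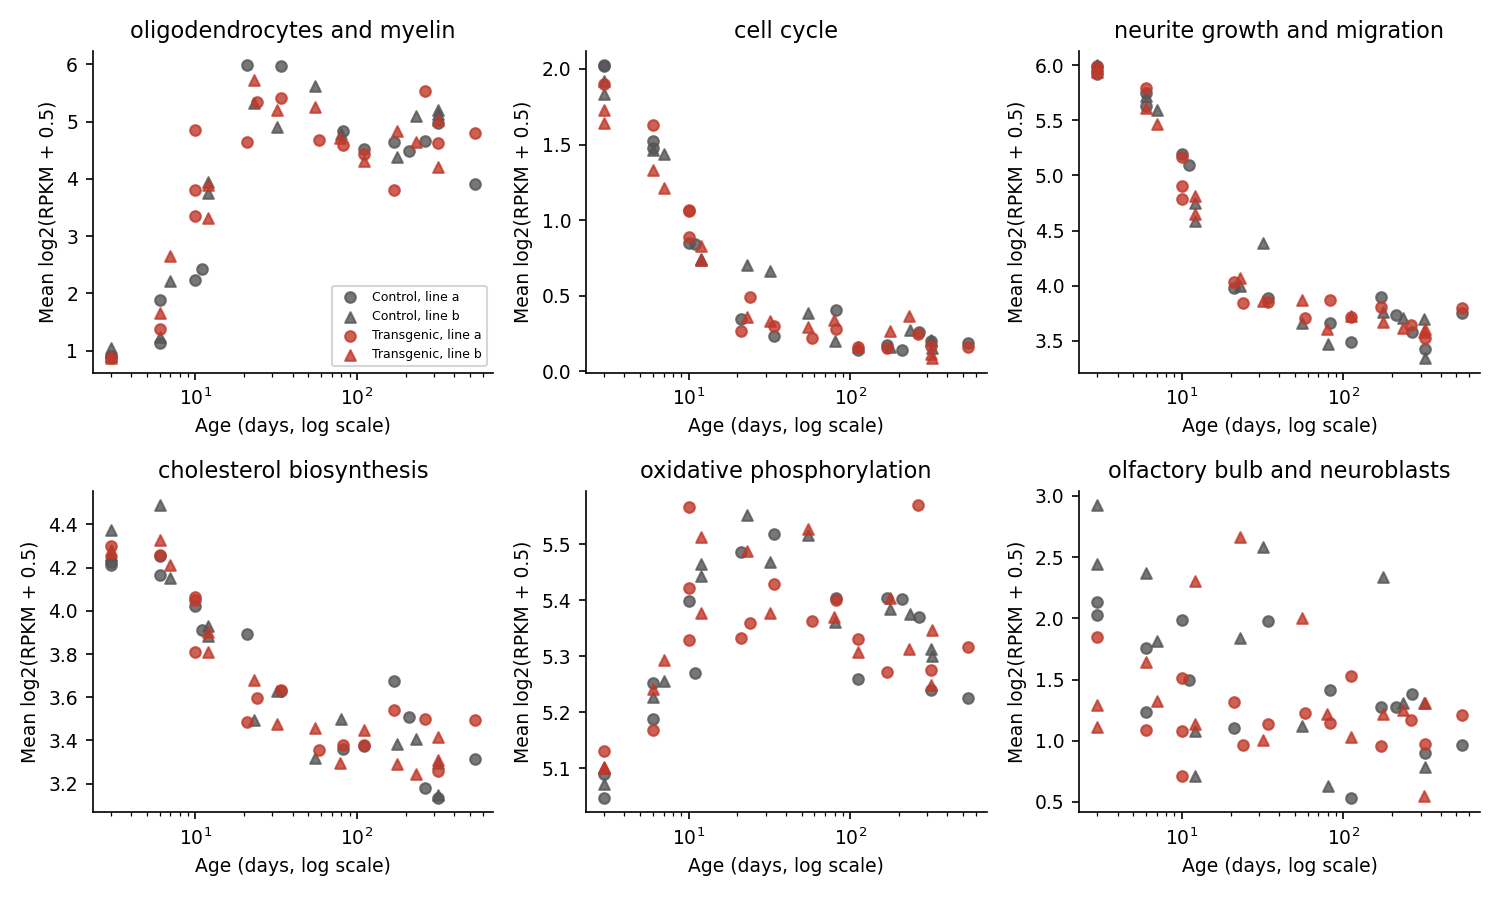
Mean log2(RPKM + 0.5) of 6 gene lists in each mouse by age. Grey marks control and red transgenic mice; circles mark line a and triangles line b.

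Whether transgenic cortex was ahead of or behind control cortex of the same age was asked with an age predicted from expression, trained on the 29 control mice. In left-out controls the predicted and actual log2 age had a Pearson r of 0.958, with a median absolute error of 0.485. In days 3–12 the predicted minus actual log2 age was 0.13 ± 0.35 (SD, n = 11) in transgenic and 0.05 ± 0.29 (SD, n = 12) in control mice. The difference was 0.086 (95% bootstrap interval -0.17 to 0.33; two-sided permutation p = 0.531). From day 21 on it was 0.19 ± 0.92 (SD, n = 19) in transgenic and -0.04 ± 0.93 (SD, n = 17) in control mice, a difference of 0.229 (-0.35 to 0.81; two-sided permutation p = 0.461). The residual from day 21 on had a Pearson r of -0.955 with age, and mean log2 age was 6.87 in control and 6.64 in transgenic mice. With the residual also corrected for age and line, the differences were 0.069 in days 3–12 (two-sided permutation p = 0.504) and 0.089 from day 21 on (two-sided permutation p = 0.153). In simulated data for days 3–12 a shift of 0.5 in log2 age was detected in 4 of 4 runs, with a mean estimate of 0.624. That simulation used independent noise per gene, while some gene lists varied together between mice in the data. It may therefore overstate how well such a shift could be detected. No shift was simulated from day 21 on.

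**Figure D4:**
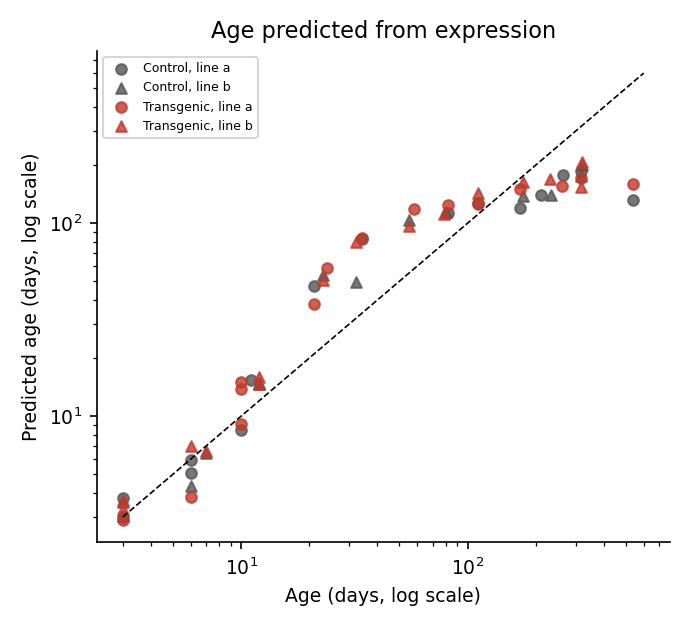
Age predicted from expression against actual age in each mouse, with the line of identity. Control mice were predicted by models that left them out.

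The labelled sex was checked against sex-linked genes. Xist, the RNA that silences an X chromosome in females, was at least 39.8 RPKM in each of the 28 females and at most 0.242 RPKM in each of the 31 males. Ddx3y, a gene of the Y chromosome, was at least 6.94 RPKM in males and at most 0.0545 RPKM in females, so that 59 of 59 labels matched. Of 16403 genes, 9 were higher in females and 4 in males. Xist stood at 6.57 ± 0.06 (SE; adjusted p = 7.23e-62), and Kdm5c and Ddx3x, which escape X inactivation, at 0.29 ± 0.02 (SE) and 0.32 ± 0.03 (SE). The Y-linked genes Ddx3y (-4.54), Eif2s3y (-4.44), Kdm5d (-3.23) and Uty (-2.30) were higher in males.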

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

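Chosen only after the result was seen were the tests of reads of the human BAC and of the chromosome region for Slc35e2, the test of carry-over for GLUD2 and the tests of explanations for the mice of days 21–34, whose fit as a stage of their own was planned, while the relation of GLUD2 and Glud1 reads was planned and its comparison in RPKM was added after its r was seen. The fit of the 9 mice of days 21–34 alone was added after their group means had been looked at, and the covariate for olfactory bulb and neuroblasts after that.

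Slc35e2 was higher in transgenic mice of line a and not in those of line b, and the interaction with line differed by 0.5725 (adjusted p = 2.1e-05; n = 30 for line a and 29 for line b). If reads of the human BAC had been counted at Slc35e2, line b, which also expressed the BAC rows, should have shown at least 0.287, a share of 0.5 of the line a effect, but its upper 95% limit was 0.1131, which argues against this. A change of the whole region in line a was argued against by the 40 nearest tested genes on chromosome 4, whose median log2 effect in line a was 0.008935 (95% bootstrap interval -0.0023 to 0.046) and of which 0 passed in limma. In line a, 1 mouse gene passed, and chance could not be excluded for that count (6 of 100 groupings gave as many, the highest other being 1859). That count takes in any gene and does not test Slc35e2 by name. For Slc35e2 in line a the adjusted p in limma was 8.07e-11. Permutation of mice within stage gave a two-sided p of 1e-05, the smallest possible. What stays open is an insertion of the BAC at or near Slc35e2, or a variant carried along with it, neither of which was tested.

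GLUD2 had reads in control mice, 270 summed over 29 libraries with 3 to 18 in each, against 72 to 254 in each transgenic library. Carry-over of reads from transgenic libraries should have brought 357 reads of lincBAC into the controls, but 9 were found (95% Poisson interval 4.1 to 17.1), which argues against it. If reads of mouse Glud1 were counted at GLUD2, the reads of both should rise together among controls, and their Pearson r was 0.5382 (n = 29; two-sided permutation p = 0.0023; 0.15 in days 3–12 and 0.78 from day 21 on). The condition set beforehand was met, but read counts of both genes also rise with depth, and in RPKM, a condition that was added later, r was 0.312 (two-sided permutation p = 0.0966), with -0.25 in days 3–12 and 0.67 from day 21 on. A contribution of Glud1 therefore stays open, since the relation in RPKM differed in sign between the stages, and no biological explanation was tested.

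When days 21–34 were fitted as a stage of their own, 71 mouse genes differed in the 5 transgenic mice, 67 of them lower, and 160 genes differed in their effect between days 21–34 and days 55–538. The lower genes include Mdh2 of the malate-aspartate shuttle (98.9 ± 5.17 RPKM, SD, n = 5, against 112 ± 2.74, SD, n = 4) and the replication gene Mcm2 (1.08 ± 0.235, SD, n = 5, against 1.59 ± 0.073, SD, n = 4), and 59 of the 67 (against 36.9% of all genes) also fall between the stages in controls, a comparison that shares the 4 control mice. Under a different share of hypothalamus, striatum, choroid plexus or olfactory bulb, covariates for them should have shrunk the median effect over these genes. The condition set was a fall below a share of 0.5, and it was not met. That median was -0.286 without covariates, -0.278 with those for the first 3 and -0.2691 with all 4. The genes were chosen by their effect in the same mice, so their median is a weak test of tissue share. With all 4 covariates 173 genes passed, so the count itself moved with this adjustment. A different share of neighbouring tissue was therefore not excluded. Another 3 explanations stay open. Transgenic mice could be further along in development (difference in predicted log2 age 0.1053, exact two-sided p = 0.524). An age curve over all mice could miss the bend at this age. In the 9 mice alone the median was -0.146, with 2 genes past the threshold and 1226 at unadjusted p under 0.05. The median difference of the group means was -0.148, against -0.286 in the fit of all mice. The fit of all mice thus gave a larger effect than the 9 mice themselves showed. The last explanation is chance. Chance could not be excluded for the 71 genes (28 of 100 groupings gave as many, the highest other being 556) or for the 160 genes (14 of 100, the highest other being 768), and groupings with several times as many genes point to a structure of the samples. Both counts depended on single mice: the 71 genes became 358, 241 and 173 without control mice 13, 14 and 16 and 14, 15, 0, 5 and 1 without transgenic mice 41 to 45 in order, the 160 became 454, 328 and 222 without control mice 13, 14 and 16 and 22, 93, 0, 7 and 43 without transgenic mice 41 to 45, and 17 genes passed without the 10 libraries highest in hypothalamic markers.

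The effect on lincBAC differed between days 3–12 and day 21 and later by -0.9467 on the log2 scale (SE 0.12; n = 23 and 36). Values far from the others of their group by a Dixon test were lincBAC in control mouse 10 of line a (0.09609 RPKM), lincBAC in control mouse 16 of line a (0.149 RPKM) and Slc35e2 in control mouse 2 of line a (6.042 RPKM). The Dixon test was run in 39 groups, 3 of which had such a value, and chance alone gives one in about 1 of 20 groups. That rate does not hold for the lincBAC values, since most other values of their groups were 0. No control library had over 4 reads of lincBAC, so these flags follow from the floor.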

How the results depend on the processing

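Chosen after results were seen were the fits without the 10 libraries highest in hypothalamic markers, those with hypothalamic, GC or neuroblast covariates, those without 1 mouse in turn and the change with age from day 55 on. Of the counts, shifts and correlations reported, 147 were kept over the alternatives and 10 were not, not counting the fits without each of the 59 mice. Counts were taken as kept within 1.5-fold of the main count, and r within the spread of the groupings. By this rule a genotype count that went from 3 to 2 was kept, even where only the transgene rows were left. Kept counts therefore say little about single mouse genes. Slc35e2 kept its call in 13 of 14 alternatives over all ages and in 12 of 17 from day 21 on. Age shifts were judged by direction and side of the threshold. The r between lines, 0.124, was kept by this rule, though it was -0.0097 without the transgene rows. Of values for named genes and lists, 1366 kept their direction and side of the threshold, 21 gained and 55 lost a call and 7 reversed. The count of 3 genes in days 3–12 was 5 with quantile normalization, 5 with median-ratio scaling, 6 with array weights, 10 with the GC slope of each library as a covariate and 6 with only the mice of days 3–12, the 3 genes being shared each time. The count from day 21 on was 73 with days 21–34 as a stage of their own, of which 2 were shared. The interaction with stage went from 1 to 2 genes without the 10 libraries highest in hypothalamic markers, and the interaction with line from 1 to 2 with array weights. The 46 list calls fell to 0 with an estimated correlation. The preset was 0.01, while the mean pairwise r between members was 0.84 for striatum and 0.36 for oxidative phosphorylation, lists that were called. It was 0.005 for glutamate transport and receptors, a list not called. The 88 genes changing with age from day 55 on became 44 without the 2 mice of day 538, 37 of them shared. Reversed values were those of Glud1, none past the threshold. From day 21 on it was -0.01 in the main fit and -0.2173 to -0.003476 in the alternatives that kept its sign. There it was 0.0002917 with striatal and choroid covariates, 0.02892 without the 10 libraries, 0.03594 with only the mice of that stage and 0.08433 for days 55–538. In line a it was 0.01 in the main fit and 0.008666 to 0.03991 in the alternatives that kept its sign. It was -0.02733 there with array weights and -0.007438 with the GC covariate, and in the interaction with line it was 0.003763 with 3 tissue covariates. Except where fewer mice were used, the cause was not tested. Leaving out each of the 5 transgenic line a mice of days 3–12 in turn gave an r between lines of 0.1453 to 0.2848. The stage effect in controls ranged from 8542 genes with the stricter filter to 11660 with none, and the sex effect from 9 to 13. Without each mouse in turn the counts ranged from 3 to 4 over all ages, 2 to 7 in days 3–12, 2 to 3 from day 21 on, 3 to 4 in line a, 2 to 2 in line b, 1 to 3 and 1 to 1 in the interactions with stage and line, 10613 to 11142 in the stage effect and 40 to 55 for list calls. No paired analysis was possible because the groups share no replicate numbers to pair by, and a matching of mice on line, sex and age, which the labels would allow for some, was not analysed here. Depth limits the precision of low values: at about 10.2 M reads, GLUD2 in controls rested on 3 to 18 reads per library.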

Other observations

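Chosen after the data were seen were the change with age from day 55 on, the list of hypothalamic markers and the agreement between lines without the transgene rows, while the groupings of the other results were planned.

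Ageing was described in the 27 mice from day 55 on, as the log2 change per doubling of age. Of 16403 genes, 19 rose and 69 fell (2194 at unadjusted p under 0.05). Among the rises were the complement gene C4b (0.44 ± 0.09, SE; adjusted p = 0.0202), the microglial protease Ctss (0.19 ± 0.03, SE), the histocompatibility gene H2-Q6 (0.41 ± 0.07, SE), the lipid transporter Abca8a (0.52 ± 0.07, SE; adjusted p = 0.00128) and the nuclear RNA gene Neat1 (0.31 ± 0.05, SE; adjusted p = 0.00638). Among the falls were Sox4, a transcription factor gene (-0.30 ± 0.06, SE), Nrep (-0.35 ± 0.06, SE) and the receptor gene Gpr17 (-0.19 ± 0.04, SE; adjusted p = 0.0358). By list, oxidative phosphorylation (FDR = 2.8e-12), immediate early genes (0.00383), excitatory neurons (0.026), cell cycle (0.0273) and endothelium (0.0273) were called lower, and microglia (0.00364), choroid plexus (0.0109) and interferon response (0.0376) higher, each with adjusted p = 0.779 with an estimated correlation. No tissue covariate was fitted here, so age was not separated from the share of neighbouring tissue. Mouse 59 of day 538 had the highest Avp and Hcrt of all libraries, and control mouse 28 of day 319 the highest mean level of choroid plexus markers. Few groupings gave as many as the 88 genes (2 of 100, the real one included), but the other one called 1384. Chance is therefore not excluded for this count, and 44 genes passed without the 2 mice of day 538.

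Some gene lists varied together between mice after age, line, sex and genotype were removed. The mean pairwise r was 0.93 for blood, 0.84 for myelin, 0.84 for striatum and 0.51 for choroid plexus, but 0.005 for glutamate transport and receptors. Hypothalamic markers had a mean pairwise r of 0.563 over 16 genes, and their mean level followed the first component of the residuals (17.6% of variance; absolute r = 0.828), while striatal markers followed the second (7.59%; absolute r = 0.921). The hypothalamic neuropeptide gene Avp reached 114 RPKM in mouse 59 against a median of 0.515, Oxt 70.8 RPKM in mouse 49 against 0.198, Hcrt 40.6 RPKM in mouse 59 against 0.132 and Pomc 47.1 RPKM in mouse 34 against 1.03. Hypothalamic markers differed between transgenic and control mice by 0.073 on the log2 scale (two-sided permutation p = 0.763).

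Other groupings of the same mice were compared with the real one, 100 in all with the real one among them. For sex 2 of 100 gave as many genes (13 genes, the highest other being 1254), and for the stage effect in controls 1 of 100 did (10960 genes; 9251). The genotype counts include the 2 transgene rows, which differ between the genotypes by design, so their groupings say little about mouse genes. With these rows they were 2 of 100 over all ages (3 genes; 18), 4 of 100 in line a (3 genes; 1859), 1 of 100 in line b (2 genes; 1), 18 of 100 in days 3–12 (3 genes; 359), 5 of 100 from day 21 on (3 genes; 222) and 21 of 100 for the interaction with stage (1 gene; 215). Without the transgene rows, chance could not be excluded for the count of genes over all ages (1 gene; 5 of 100, 18), in days 3–12 (1 gene; 23 of 100, 359), from day 21 on (1 gene; 15 of 100, 222), in line a (1 gene; 6 of 100, 1859) or for the interaction with line (1 gene; 6 of 100, 215). In line b and in the interaction with stage no mouse gene passed in limma (498 and 999 genes at unadjusted p under 0.05). The agreement between lines was as high in 30 of 100 groupings over all ages (r = 0.124, the highest other being 0.343) and in 36 of 100 in days 3–12 (0.245, 0.599). Without the transgene rows it was as high in 65 of 100 (-0.0097, 0.343) and 45 of 100 (0.211, 0.599), so that chance could not be excluded in any of the 4. Groupings that call several times the real count of genes point to a structure of the samples that the fitted models do not describe. Genotype was shuffled within line and stage but not within age, so a part of age in that structure was not tested.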
